A study of Aspergillus niger with 6 samples.

How the data were processed

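RNA was measured by sequencing in 6 libraries of Aspergillus niger cultures, 3 labelled as unexposed controls (CK1 to CK3) and 3 labelled as exposed for 7 days to volatile organic compounds of a bacterium (VOC1 to VOC3). The authors deposited a single table of whole-number counts per gene, with a column for each library. Per the submitters' processing notes, RSEM 1.3.1 and DESeq2 1.40.2 were used. The aligner and the genome build are not given in the sources used here. Since RSEM estimates can be fractional, the deposited whole counts may have been rounded by the authors. The labels' extraction protocol describes droplet barcoding of single cells, while the deposited table has no cell barcodes, so each column was analysed as a bulk library. The labels do not say that the 3 samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

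The table lists 13565 genes, all of which matched a locus tag of the RefSeq gene table of assembly ASM285v2, which was used only for names and gene order. No coordinates are printed. Genes that the gene table does not class as protein coding held between 0.047% and 0.116% of the counts of a library. Total counts per library lay between 16.06 M and 16.54 M, and 3 counts, taken as the detection floor, correspond to between 0.181 and 0.187 CPM by library totals, before TMM scaling. Bounds against a group at 0 were computed from 3 counts over the group and cover counting error only. Functions are those of the best protein match given in the deposited table. Of the 8598 descriptions, 5293 came from Quercus suber and 1986 from Carpinus fangiana, both plants, and 0 named Aspergillus. Some of these records carry names of fungal genes, such as wetA and abaA, so how close the matches are is not known. Functions are therefore by similarity alone unless a gene carries an established A. niger symbol.

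Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling, robust quasi-likelihood fits (glmQLFit, glmQLFTest) with group as the only term, and Benjamini-Hochberg adjustment at 0.05. In total 11512 genes passed the filter. All log2 fold changes are VOC minus CK. Their standard errors are approximate and were derived from the fold change and the quasi-likelihood F statistic. Levels are TMM-scaled CPM. The 35 gene lists were fixed before the data were examined, as text patterns on descriptions and KEGG text, and each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). Adjustment was over the lists, and lists needed at least 5 measured genes. Camera was repeated with an estimated correlation. Fry was also run. It tests whether the genes of a list move, on balance, in a single direction, without comparing them with other genes.

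Genes were named by a rule fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 10 CPM, non-overlapping groups and a functional description. It also took up to 3 members with the smallest adjusted p of each list described, and 19 genes fixed by symbol. Any gene outside this rule is said to have been chosen after its values were seen. The rule gave 128 genes over all 35 lists, of which a part is named in the text.

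The alternatives were RLE, upper quartile and library-size scaling, no count filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn (with the count filter run again, so the number of measured genes of a list can differ), an adjusted p under 0.01, a fold of at least 2, and a test against a fold of 1.5. A limma-voom fit with a weight for each library and a test of GO terms were added after the data were seen. The scripts were tested on simulated data. Counts were drawn for the VOC against CK comparison from the measured means and library sizes, with genes changed by known folds and a planted list of 40 genes. With an equal spread in both groups camera found the planted list. Its detection with the unequal spread is not reported here. Camera called 0 of 30 unchanged lists with either spread. Simulated genes were drawn independently, so the effect of correlation between genes on these calls was not tested. With an equal spread in both groups, edgeR, run on 11501 genes, found 86% of the 100 genes changed 4-fold and 8% of the 100 changed 2-fold, and called 10 of 11261 unchanged genes. With the measured, unequal spread of each group, edgeR, run on 11498 genes, found 17% of the 4-fold and 0% of the 2-fold changes. It called 0 of 11258 unchanged genes. DESeq2, run on 13445 genes, found 86% and 19% and called 53 of 13205. Each simulated group had a single spread for all genes, while measured spreads differ between genes. These shares therefore do not give the power in the measured data.

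For the order of neighbouring genes, tags were sorted by position within each supercontig, named by the tag's prefix. A sort by chromosome and position was used at the start and was replaced after its counts were seen, because positions in the gene table restart on each supercontig and that sort mixed genes of different supercontigs. Both sets of counts are given. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.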

Results

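The transcriptome of Aspergillus niger, a filamentous fungus that spoils fruit, was measured in 3 libraries of unexposed fungus (CK) and in 3 libraries of fungus exposed for 7 days to volatile organic compounds of a bacterium (VOC). The comparison asks how transcript levels differ after exposure to the volatiles of a fruit endophytic Bacillus. The sample labels give a day for the VOC libraries only. A difference in culture age between the groups therefore cannot be told apart from exposure. Total counts were 16.53 M, 16.54 M and 16.06 M in CK1 to CK3 and 16.23 M, 16.17 M and 16.33 M in VOC1 to VOC3. Genes listed at 0 numbered 500, 547 and 456 in the CK libraries and 1009, 718 and 974 in the VOC libraries.

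After exposure, regulators of asexual sporulation, spore pigment genes and the nitrate reductase gene fell, while several genes of starch breakdown, ribosomes, sterols and the cell wall rose. Among fixed gene lists, 5 passed camera as higher and 1 as lower, and 0 passed with an estimated correlation. The list of conidiation and pigment (10 of 17 genes lower) did not pass camera (adjusted p = 0.0643). That of nitrate and ammonium use (18 of 52 lower) did not either (adjusted p = 0.066). Nor did those of ergosterol biosynthesis and of chitin and glucan synthesis (adjusted p = 0.105 and 0.308). Fry, which does not compare a list with other genes, passed all of these but chitin and glucan synthesis. The sporulation regulator brlA fell from 378 ± 26.5 to 6.15 ± 9.01 CPM (SD, n = 3 per group) and the glucoamylase gene glaA rose from 626 ± 11.2 to 8910 ± 3580 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2302 genes rose and 2211 fell of 11512 tested. At least 8-fold changes were more often falls, with 416 genes lower and 160 higher, and at least 32-fold changes numbered 111 lower and 19 higher. For 6668 genes (57.9%) the values of the groups did not overlap. For values in random order the share is 10%, which assumes an equal spread in both groups. Spreads here were unequal, so 10% is not the share by chance. With library sizes alone as the scaling, the median of all genes shifted by -0.35 log2, and 26.5% of calls were rises in place of 51%.

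The CK libraries lay close together and the VOC libraries did not. Pearson's r of log2 CPM across genes was 0.995 for each pair of CK libraries, 0.976 between VOC1 and VOC3, and 0.917 and 0.909 between VOC2 and these. VOC2 correlated with the CK libraries at 0.906 to 0.908, and VOC1 and VOC3 at 0.797 to 0.81. The biological coefficient of variation was 5.53% in CK, 47.9% in VOC and 27.6% in VOC without VOC2. Without VOC2, 3346 genes rose and 3622 fell. Without CK1, CK2 or CK3, the rises numbered 864, 869 and 861 and the falls 1048, 1031 and 1043. The loss was alike for each CK library, so it does not point to a single one of them. Each fit estimates a single spread per gene over both groups, though the spreads of the groups were unequal. Gene calls given below without a CK library carry the same limit.

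**Figure D1:**
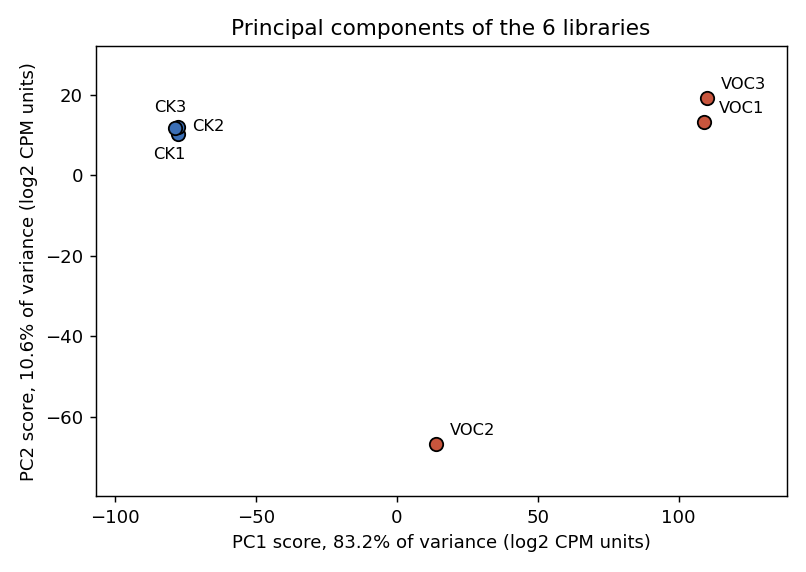
Scores of the 6 libraries on the first principal components of log2 CPM (component 1 on the x axis, 83.2% of variance, and component 2 on the y axis, 10.6%); each point is a library, blue for CK and red for VOC. The CK libraries share a score near -78 on component 1, VOC1 and VOC3 lie at 109 and 110, and VOC2 lies at 13.9. On component 2 VOC2 lies at -66.9 and the other libraries lie between 10.4 and 19.3.

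Sporulation and pigment genes included the deepest falls among the genes fixed by symbol. Expression of brlA, which starts conidiophore development, fell by 5.94 on the log2 scale (SE 1.28, adjusted p = 0.0151), and its downstream regulators abaA and wetA fell as well (-1.78, adjusted p = 0.00232, and -1.61, adjusted p = 0.00127). The pigment polyketide synthase gene fwnA fell from 2440 ± 63 to 62 ± 37.4 CPM (log2 fold change -5.30, SE 0.48, adjusted p = 0.00147). The pigment genes olvA and brnA fell to a like degree (-5.93, adjusted p = 0.0122, and -6.49, adjusted p = 0.00411). In VOC2, brlA stood at 16.6 CPM, against 0.907 and 0.99 in VOC1 and VOC3, and fwnA at 105 CPM, against 37.6 and 43.3. Without VOC2 the log2 fold changes of brlA, olvA, brnA and fwnA were -8.62, -8.20, -7.75 and -5.92. Without CK1, CK2 or CK3 the adjusted p of brlA was 0.0511, 0.052 and 0.0507. Of the 17 measured genes of the conidiation and pigment list, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with a median log2 fold change of -0.86. The list did not pass camera (adjusted p = 0.0643, and 0.788 with an estimated correlation), but it passed fry (adjusted p = 0.00265). Its falls numbered 5, 5 and 6 and its rises 0, 0 and 1 without CK1, CK2 and CK3, and 1 member rose without VOC1 or VOC3. Among its falling members was An01g08960, an iron transport oxidase match that took part through its description (log2 fold change -1.93).

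More starch hydrolase genes rose than fell. The list of starch hydrolases had 8 rises and 1 fall among 15 measured genes (8 and 1 adjusted over the list alone), with a median of 0.84, and passed camera (adjusted p = 0.0145), with an adjusted p = 0.788 with an estimated correlation. It had 6 rises and 0 falls without each CK library, and 9 rises and 2 falls without VOC2. Besides glaA (log2 fold change 3.83, SE 0.34, adjusted p = 0.00135), the alpha-glucosidase gene aglU rose by 2.39 (adjusted p = 0.00169) and the acid alpha-amylase gene An11g03340 by 4.10 (adjusted p = 0.00187). The transcription factor gene amyR, an activator of amylase genes, rose by 1.45 (adjusted p = 0.00342). Values of An05g02100 (3.88) and An12g06930 (4.44), alpha-amylase matches chosen after their values were seen, are uncertain, since near-identical amylase copies can share reads. The member that fell, An07g08640, also chosen after its value was seen, matched an alpha-1,3-glucanase, which acts on a cell wall glucan (log2 fold change -0.94). VOC2 was the lowest VOC library for glaA, at 5530 CPM against 12700 and 8520.

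A phosphate permease match and sugar transporter matches stood among the 12 largest rises. The list of major facilitator transporters had 12 rises and 19 falls among 63 measured genes. The phosphate permease match An02g00180 rose from 1.51 ± 0.254 to 327 ± 308 CPM (log2 fold change 7.75, adjusted p = 0.00418), with 57.4 CPM in VOC2 and a log2 fold change of 6.70 without VOC3. The sugar transporter matches An14g02740 and An12g07450 rose by 7.17 (adjusted p = 0.00838) and 5.85 (adjusted p = 0.00179). Limma-voom ended the call of An14g02740 (adjusted p = 0.0717). An11g00120, with the same description as An12g07450 and chosen after its values were seen, fell by at least 2-fold. The fructan-degrading inulinase gene inuA rose by 7.18 (adjusted p = 0.0176), from 0.162 ± 0.143 to 24.7 ± 20.8 CPM, with 0.878 CPM in VOC2. The adjusted p of inuA was 0.0733, 0.0696 and 0.0698 without CK1, CK2 and CK3, and 0.138 with limma-voom. The regulator genes creA (0.25, adjusted p = 0.401) and areA (-0.13, adjusted p = 0.54) did not pass the test. For xlnR the log2 fold change was -0.59 (adjusted p = 0.0558). The adjusted p of xlnR was 0.00236 without VOC2, 0.018 with library sizes alone, 0.0475 at a mean of at least 10 CPM, 0.0358 with DESeq2 and 0.0434 with limma-voom.

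The nitrate reductase gene niaD fell by 3.49 (SE 0.24, adjusted p = 0.000917), as did the nitrite reductase match An08g05640 (-5.52, SE 0.30, adjusted p = 0.000605) and the nitrate transporter match An08g05670 (-6.96, SE 0.44, adjusted p = 0.000804). In VOC2 they stood at 15.2, 13.1 and 1.49 CPM, against CK means of 142, 452 and 123 CPM. The list of nitrate and ammonium use had 18 falls and 6 rises among 52 measured genes (19 and 7 adjusted over the list alone), with a median of -0.39. It did not pass camera (adjusted p = 0.066, and 0.807 with an estimated correlation), but it passed fry (adjusted p = 0.00851). Its falls numbered 10, 11 and 11 without CK1, CK2 and CK3 and 27 without VOC2, where 10 members rose. Some of its falling members, chosen after their values were seen, do other things by description, such as An11g06770 (-0.98) and An08g10720 (-0.42), which matched subunits of the enzyme that attaches membrane anchors to proteins.

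**Figure D2:**
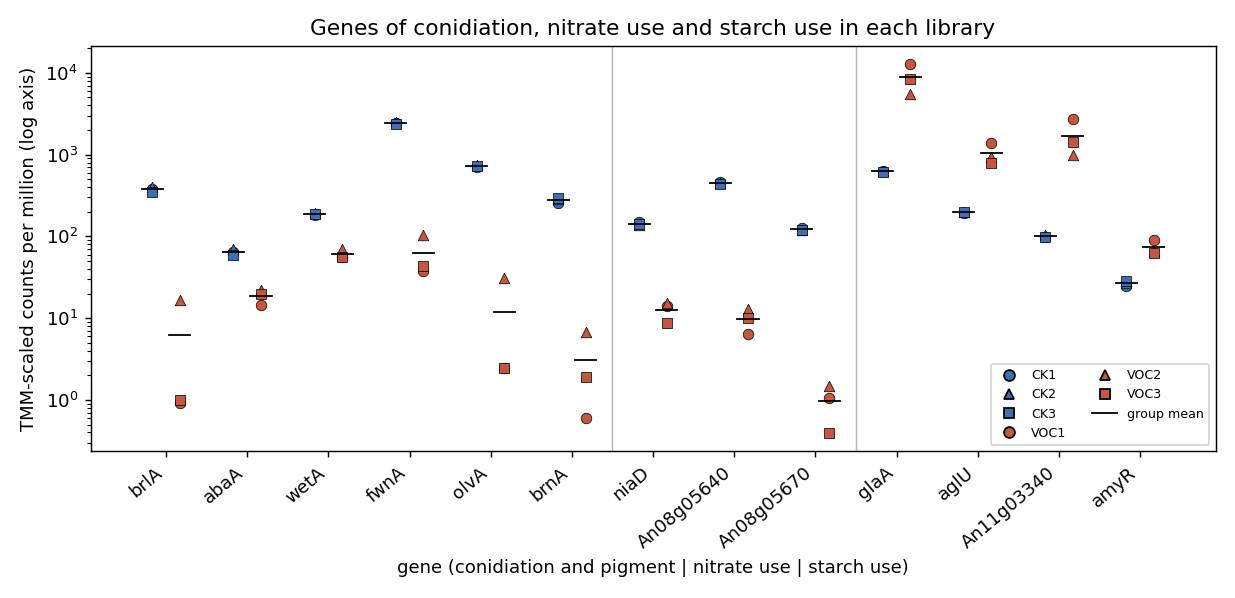
Level of 13 genes in each library, in TMM-scaled CPM on a log axis, with genes of conidiation and pigment, nitrate use and starch use from left to right; blue points are CK and red points VOC libraries, with shapes for replicates and bars for group means. For brlA the VOC libraries lie at 0.907, 16.6 and 0.99 CPM, with VOC2 (triangle) nearest the CK mean of 378, and for glaA VOC2 is the lowest VOC library at 5530 CPM.

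Ribosomal genes rose by small amounts in large number. Of 97 measured genes of the cytosolic ribosomal list, 69 rose and 0 fell (81 and 0 adjusted over the list alone), with a median of 0.53 and a camera adjusted p = 5.81e-13. The mitochondrial ribosomal list had 23 rises among 30 genes (28 adjusted over the list alone), a median of 0.65 and an adjusted p = 5.01e-08. Ribosome biogenesis had 27 rises among 49 (33 adjusted over the list alone), a median of 0.69 and an adjusted p = 1.3e-06. With an estimated correlation the camera adjusted p was 0.788, 0.788 and 0.807 for these lists. Members of these lists with small adjusted p were the ribosome biogenesis match An07g07010 (1.15, adjusted p = 0.00206) and the mitochondrial ribosomal matches An18g02990 (1.09, adjusted p = 0.00311) and An04g07330 (0.98, adjusted p = 0.00354). With library sizes alone the medians stayed above 0, at 0.18, 0.30 and 0.35, while 6, 10 and 4 genes rose. Without CK1, CK2 or CK3, 9, 8 and 7 genes of the cytosolic list rose, 10, 13 and 9 of the mitochondrial list and 3, 3 and 3 of ribosome biogenesis. Of the cytosolic list, 20 genes carried organellar or bacterial-type names and 15 of them rose. Without VOC2, 85, 25 and 39 genes of these lists rose and 0, 1 and 0 fell.

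Counts of the respiratory list changed when a library was left out. Of 54 genes of the respiratory chain and ATP synthase list, 9 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.25 that was -0.10 with library sizes alone. The camera adjusted p was 0.0367, against 0.807 with an estimated correlation and 0.476 with library sizes alone. It was 0.054, 0.0629, 0.0968 and 0.135 without CK2, CK3, VOC1 and VOC2, and 6e-05 without VOC3. The list had 1, 1 and 1 rises without CK1, CK2 and CK3, 5 without VOC1 and 18 without VOC3. The cytochrome c1 match An04g06510 rose by 1.04 (adjusted p = 0.0103, and 0.0588, 0.0563 and 0.0541 without CK1, CK2 and CK3). The alternative oxidase gene aox1, whose enzyme bypasses part of the chain, rose by 3.82 (SE 0.84, adjusted p = 0.0161), with 3970, 606 and 655 CPM in VOC1, VOC2 and VOC3, and its log2 fold change was 2.34 without VOC1. The adjusted p of aox1 was 0.0694, 0.0711 and 0.07 without CK1, CK2 and CK3. The glycolysis list had 8 rises and 2 falls among 19 genes (9 and 2 adjusted over the list alone), with the glyceraldehyde-3-phosphate dehydrogenase gene gpdA at 0.90 (adjusted p = 0.00594), and did not pass camera (adjusted p = 0.11). Without CK1, CK2 and CK3 its rises numbered 3, 4 and 3 and its falls 0, 0 and 0.

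Fatty acid beta-oxidation and peroxisome was the list that passed camera as lower. Of 51 genes 17 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.46 and a camera adjusted p = 0.0113, against 0.807 with an estimated correlation and 0.0571 without VOC1. The carnitine acetyltransferase match An08g04990 fell by 0.84 (adjusted p = 0.00414), as did the peroxin-1 match An16g04880 (-1.02, adjusted p = 0.005) and the peroxisomal membrane match An12g03650 (-0.86, adjusted p = 0.00643). Without VOC2, 36 of 52 genes of the list fell, 5, 6 and 6 fell without CK1, CK2 and CK3, and 11 and 10 fell without VOC1 and VOC3.

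Ergosterol genes, which make the main fungal membrane sterol, rose in part. Of 38 measured genes 11 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.30 that was -0.05 with library sizes alone. The list did not pass camera (adjusted p = 0.105, and 0.807 with an estimated correlation), but it passed fry (adjusted p = 0.0385). Its rises numbered 6, 6 and 5 without CK1, CK2 and CK3, and without VOC2 it had 17 rises and 5 falls. The GO term ergosterol biosynthetic process, tested after the data were seen, held 39 genes with 15 rises and 2 falls. That term passed camera as higher (adjusted p = 0.0203), but not with an estimated correlation. The sterol reductase match An01g07000 rose by 2.32 (adjusted p = 0.00227), the methylsterol monooxygenase match An03g06410 by 2.04 (adjusted p = 0.00293) and the sterol methyltransferase match An14g01590 by 1.16 (adjusted p = 0.00459). The gene of the azole target, cyp51A, rose by 0.87 (adjusted p = 0.0463), with 388, 184 and 246 CPM in the VOC libraries. Its adjusted p was 0.139, 0.127, 0.14, 0.0543 and 0.0756 without CK1, CK2, CK3, VOC1 and VOC3, and 0.13 with library sizes alone, where its log2 fold change was 0.49. At a mean of at least 10 CPM the adjusted p of cyp51A was 0.0559.

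Cell wall synthesis genes moved both ways, with 19 rises and 9 falls among 58 genes of chitin and glucan synthesis (21 and 10 adjusted over the list alone), a median of 0.21 that was -0.14 with library sizes alone, and a camera adjusted p = 0.308. The rises of this list numbered 7, 6 and 7 and the falls 6, 6 and 6 without CK1, CK2 and CK3. There were 12 rises without VOC1, and 28 rises and 15 falls without VOC2. The alpha-1,3-glucan synthase gene agsA rose by 1.95 (adjusted p = 0.00126), the chitin synthase match An07g05570 by 1.48 (adjusted p = 0.00112) and agsE by 1.46 (adjusted p = 0.0219). The call of agsE ended without CK1, CK2, CK3, VOC1 or VOC3, with adjusted p values of 0.0813, 0.0831, 0.0873, 0.0577 and 0.0592. For gfaA, which feeds chitin synthesis, the log2 fold change was 0.77 (adjusted p = 0.0525), and the adjusted p was 0.000577 without VOC2 and 0.0221 with DESeq2. Among 25 genes of cell wall hydrolysis 7 fell and 6 rose (7 and 6 adjusted over the list alone), with the chitinase match An09g05920 at -2.80 (adjusted p = 0.000981) and the chitinase match An04g04670 at 2.01 (adjusted p = 0.00108). VOC2 lay near the other VOC libraries for both, at 9.93 and 330 CPM.

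Of 36 antioxidant genes 8 rose and 8 fell (9 and 9 adjusted over the list alone). Without VOC2, 10 rose and 16 fell and the median turned from 0.18 to -0.31, and 4 rose and 4 fell without each CK library. The superoxide dismutase match An01g12530 rose by 3.75 (adjusted p = 0.00154) and the catalase match An01g01550 by 4.04 (adjusted p = 0.00419), with 214 CPM in VOC2 against 922 and 730. For catR, a catalase gene, the log2 fold change was 1.67 (adjusted p = 0.0885) with 107, 359 and 56.7 CPM in the VOC libraries, and the log2 fold change was 0.58 without VOC2, while the adjusted p was 0.0304 without VOC3 and 0.0171 with DESeq2. Of 42 ABC transporters 12 rose and 9 fell (12 and 10 adjusted over the list alone), with the smallest adjusted p for An01g12380 at 2.17 (adjusted p = 0.00068) and An07g07500 at -1.66 (adjusted p = 0.000887). Of 45 heat shock genes 13 rose and 5 fell (13 and 5 adjusted over the list alone), including the small heat shock match An03g00400 at 3.71 (adjusted p = 0.000998) and the HSP90 gene sspB at 1.26 (adjusted p = 0.00452). None of these 3 lists passed camera (adjusted p = 0.77, 0.986 and 0.219). Fry passed the heat shock list (adjusted p = 0.0385) and not the antioxidant and ABC transporter lists (adjusted p = 0.907 and 0.399). Without VOC2 the ABC transporters had 15 rises and 15 falls and the heat shock genes 17 and 9. Without CK1, CK2 and CK3 the rises numbered 4, 4 and 4 and 5, 6 and 5, and the falls 5, 7 and 6 and 3, 3 and 3.

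The deepest falls included matches to secondary metabolism genes. The acyl-CoA synthetase match An12g02750 had 21.9 ± 1.04 CPM in CK and 0 counts in all 3 VOC libraries, at least 315-fold lower by the floor of 3 counts over the group. In the same stretch of genes, An12g02730, a reducing polyketide synthase match, fell from 46.1 ± 4.19 to 0.228 ± 0.331 CPM (-7.60, adjusted p = 0.00196). The acetolactate synthase match An03g00480, an enzyme of branched-chain amino acid synthesis, also fell (-7.48, adjusted p = 0.00683). Without VOC2 the log2 fold changes of An12g02730 and An03g00480 were -10.08 and -11.08, and without VOC3 -7.01 and -6.89. Of 32 polyketide and nonribosomal peptide synthase genes 12 fell and 8 rose (14 and 9 adjusted over the list alone), with a median of -0.53 and a camera adjusted p = 0.201. Its rises numbered 4, 4 and 5 without CK1, CK2 and CK3. The acid-forming enzyme gene oahA, which makes oxalate from oxaloacetate, rose by 1.84 (adjusted p = 0.00174), while the glucose oxidase gene goxC did not pass (0.94, adjusted p = 0.40, and -0.48 without VOC2).

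**Figure D3:**
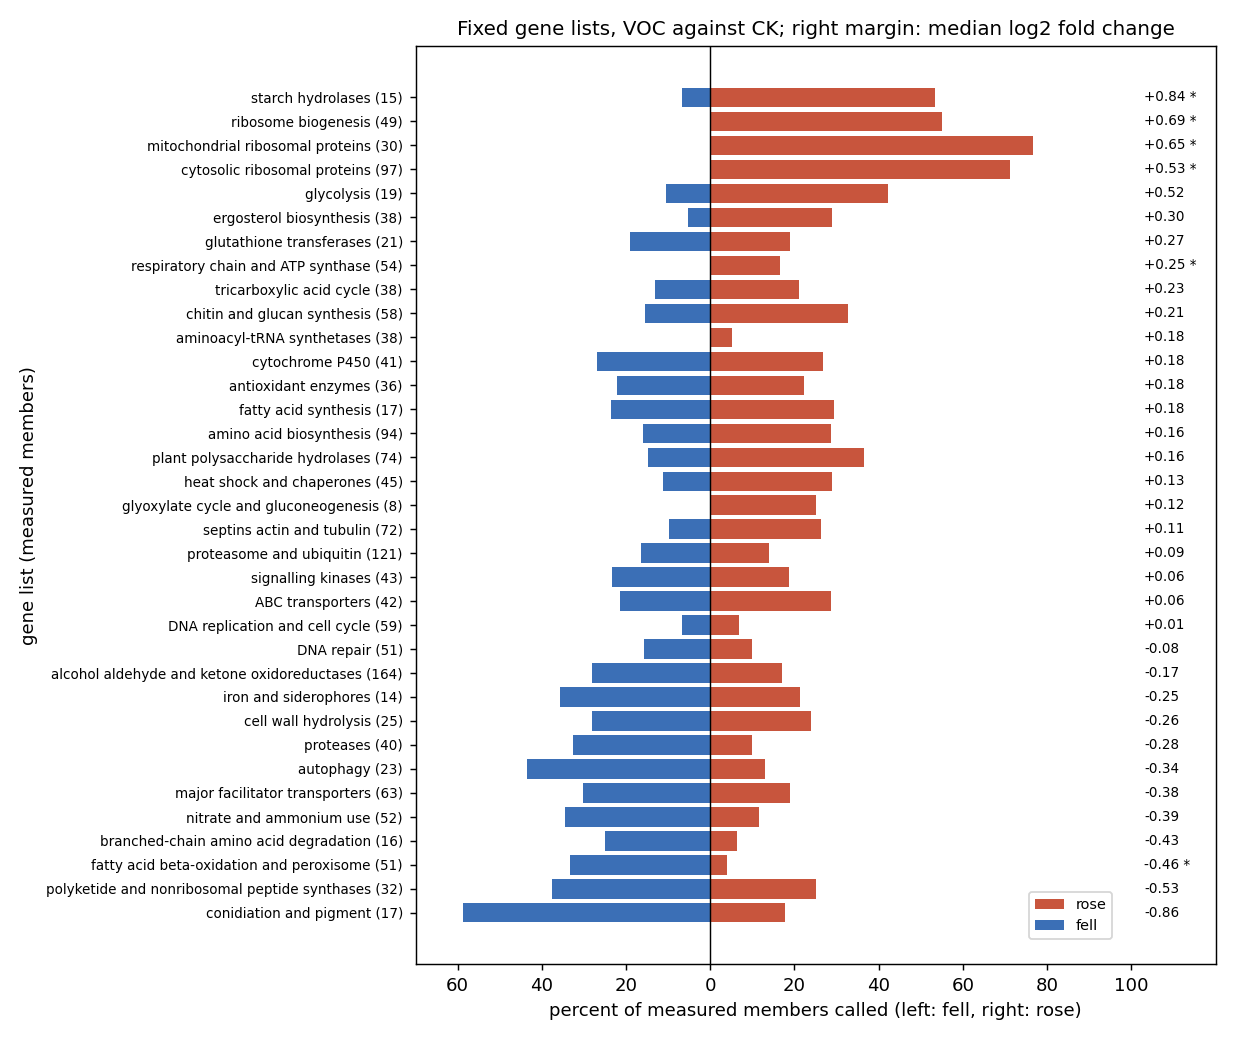
Percent of the measured members of each of the 35 fixed lists that rose (right, red) or fell (left, blue), with the number measured after each name and the median log2 fold change at the right; a star marks a camera adjusted p below 0.05 with a preset correlation. The ribosomal lists have 69 of 97, 23 of 30 and 27 of 49 members higher, and the conidiation and pigment list has 10 of 17 lower.

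In the remaining lists, the counts of rises and falls were 27 and 11 of 74 for plant polysaccharide hydrolases, 27 and 15 of 94 for amino acid biosynthesis, 19 and 7 of 72 for septins, actin and tubulin, and 8 and 5 of 38 for the tricarboxylic acid cycle. They were 2 and 0 of 38 for aminoacyl-tRNA synthetases, 2 and 0 of 8 for the glyoxylate cycle, 5 and 4 of 17 for fatty acid synthesis, 4 and 4 of 21 for glutathione transferases and 11 and 11 of 41 for cytochrome P450. They were 12 and 19 of 63 for major facilitator transporters, 4 and 13 of 40 for proteases, 3 and 10 of 23 for autophagy, 28 and 46 of 164 for alcohol, aldehyde and ketone oxidoreductases and 3 and 5 of 14 for iron and siderophores. They were 1 and 4 of 16 for branched-chain amino acid degradation, 8 and 10 of 43 for signalling kinases, 17 and 20 of 121 for proteasome and ubiquitin, 5 and 8 of 51 for DNA repair and 4 and 4 of 59 for DNA replication. None of these passed camera.

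Leaving out 1 library moved most counts of these remaining lists by more than 1.5 times. Without VOC2 the rises and falls were 32 and 20 for plant polysaccharide hydrolases, 32 and 25 for amino acid biosynthesis, 30 and 10 for septins, actin and tubulin and 10 and 8 for the tricarboxylic acid cycle. They were 8 and 0 for aminoacyl-tRNA synthetases, 2 and 2 for the glyoxylate cycle, 4 and 15 for glutathione transferases and 13 and 17 for cytochrome P450. Transporters of the major facilitator family had 15 and 32, with 38 and 79 for the oxidoreductases and 1 and 11 for branched-chain amino acid degradation. Rises and falls were 14 and 13 for signalling kinases, 32 and 22 for proteasome and ubiquitin, 13 and 10 for DNA repair and 18 and 11 for DNA replication. The median of glutathione transferases turned from 0.27 to -0.91 without VOC2 (camera adjusted p = 0.0779). With a CK library left out in turn, the ranges of rises and falls were 9 to 10 and 7 to 8 for plant polysaccharide hydrolases, 9 to 11 and 6 to 8 for amino acid biosynthesis, 6 to 7 and 5 for septins, actin and tubulin and 4 and 1 for the tricarboxylic acid cycle. They were 0 and 0 for aminoacyl-tRNA synthetases, 1 and 0 for the glyoxylate cycle, 2 and 0 to 1 for glutathione transferases and 1 and 7 to 8 for cytochrome P450. The ranges were 5 to 6 and 10 to 11 for major facilitator transporters, 12 to 14 and 19 to 23 for the oxidoreductases and 1 and 2 for branched-chain amino acid degradation. For other lists they were 4 and 5 to 6 for signalling kinases, 6 and 5 to 6 for proteasome and ubiquitin, 0 to 2 and 3 for DNA repair and 0 and 0 to 1 for DNA replication. Lists not moved that far by VOC2 had 0 and 4 for fatty acid synthesis, 3 and 7 to 8 for proteases, 0 and 4 to 5 for autophagy and 0 and 3 to 4 for iron and siderophores. Without VOC3 the tricarboxylic acid cycle had 15 rises and 3 falls and passed camera (adjusted p = 0.0131), DNA repair had 2 rises and DNA replication 2. Without VOC1, aminoacyl-tRNA synthetases had 5 rises, fatty acid synthesis 3 rises and glutathione transferases 2 falls, and without VOC1 or VOC3 iron and siderophores had 0 rises.

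Adjusted over the list alone, the counts of the remaining lists were 29 and 14 for plant polysaccharide hydrolases, 28 and 15 for amino acid biosynthesis, 5 and 13 for proteases, 3 and 12 for autophagy, 18 and 7 for septins, actin and tubulin, 8 and 3 for the tricarboxylic acid cycle and 0 and 0 for aminoacyl-tRNA synthetases. They were 13 and 19 for major facilitator transporters, 30 and 48 for the oxidoreductases, 1 and 3 for branched-chain amino acid degradation, 15 and 15 for proteasome and ubiquitin, 4 and 6 for DNA repair and 2 and 1 for DNA replication, and unchanged for the others. With library sizes alone, the median changed sign from positive to negative in all of the remaining lists whose median was above 0. The median was above 0 while camera pointed down for glutathione transferases, ABC transporters, fatty acid synthesis, signalling kinases and DNA replication, and the mean was below 0 while camera pointed up for antioxidant enzymes and cytochrome P450. With an estimated correlation 0 of the 35 lists passed camera (1 had an unadjusted p below 0.05), and the smallest adjusted p was 0.788. Fry passed 15. As higher it passed ergosterol biosynthesis, heat shock, glycolysis, starch hydrolases and cytosolic and mitochondrial ribosomal proteins. As lower it passed conidiation and pigment, nitrate and ammonium use, polyketide and nonribosomal peptide synthases, cell wall hydrolysis and proteases. Autophagy, fatty acid synthesis, iron and siderophores and major facilitator transporters also passed as lower. Ribosome biogenesis, the respiratory chain and beta-oxidation passed camera but not fry.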

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

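The fit with a weight for each library was chosen after the data were seen. Rises (2302) and falls (2211) moved to 1266 and 3514 with library sizes alone, 891 and 960 at an adjusted p under 0.01, and 1017 and 1135 against a fold of 1.5, where a fold of at least 2 left 1386 rises and 1508 falls. The stricter thresholds keep fewer genes by construction. Leaving out each library gave 861 to 3346 rises and 1031 to 3622 falls, lowest without a CK library and highest without VOC2. The loss was alike for each CK library, and each fit estimates a single spread per gene over groups of unequal spread. DESeq2 gave 2744 and 2517 (867 genes had no adjusted p), limma-voom 2147 and 2577, and limma-voom with library weights (0.127 for VOC2, 3.99 for CK1) 2779 and 2792. The other scalings and filters stayed within 1.5 times. Gene lists passing camera numbered 5 higher and 1 lower, 0 and 0 with an estimated correlation, 6 and 9 by fry, which shared 3 and 0 of them, and 4 and 2 at a mean of at least 10 CPM. Leaving out each library gave 4 to 6 higher and 0 to 1 lower, with 0 without VOC1. Of the 128 named genes, 0 changed direction while past the threshold under any setting run, and the calls lost numbered 10 with library sizes alone, 8 with the replicate block, 19, 18 and 20 without CK1, CK2 and CK3, and 4 with limma-voom. The replicate block gave 1395 rises and 1524 falls, and 4 lists higher, without the respiratory chain list (camera adjusted p = 0.0516). Correlations of same-numbered deviations were -0.06, -0.03 and -0.03, and no library correlated best with its own number. The CK libraries differed little (biological coefficient of variation 5.53%), so this check cannot tell whether the shared numbers pair the samples. The cause of the other changes was not tested. At this depth 3 counts equal at most 0.187 CPM by library totals, so genes near that level cannot be compared. In TMM-scaled CPM this floor is higher in VOC1, VOC2 and VOC3, whose scaling factors were 0.815, 0.916 and 0.928.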

Other observations

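The GO terms, all tests on VOC2, the scaling test of the ribosome genes and the gene order used for neighbouring genes were chosen after the results were seen. Among 2582 GO terms tested with camera, 138 were higher and 5 lower, and 0 passed with an estimated correlation, where 16 had an unadjusted p below 0.05. Terms share genes, so these counts exceed the number of separate processes. All lower terms were polyamine or ammonium transport terms, with the same counts within each kind. Many higher terms were overlapping terms of ribosomes, rRNA processing and translation. The term polyamine transport held 14 measured genes, of which 10 fell and 0 rose, with a median log2 fold change of -1.91 (adjusted p = 0.000567, and 1 with an estimated correlation). Ammonium transmembrane transport held 18 genes with 11 falls and 2 rises (median -1.21, adjusted p = 0.0278). Hyphal tip held 18 genes with 11 rises and 0 falls (median 0.88, adjusted p = 0.0176), and isoleucine biosynthetic process 10 genes with 7 rises and 1 fall (median 1.12, adjusted p = 0.0204). For these 3 terms too the adjusted p was 1 with an estimated correlation.

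VOC2 also held transcripts at higher levels than the other libraries. In VOC2, 256 genes stood at least 2-fold above every other library, against 154 in VOC1 and 132 in VOC3. The nitroreductase match An14g07060 stood at 1930 CPM in VOC2, against 201 and 119 in VOC1 and VOC3 and a mean of 362 in CK. The glutathione S-transferase match An01g09610 stood at 487 CPM, against 96.6, 65.6 and 72.2. Both were chosen after their values were seen.

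Genes changed by at least 2-fold lay next to each other more often than in shuffled orders. The falls formed 44 runs of at least 4 neighbouring tested genes, holding 224 genes, against a median of 3 and a highest of 11 in 1000 shuffled orders (permutation p = 0.001, 1-sided, the smallest that number can give). The rises formed 34 runs with 166 genes, against a median of 2 and a highest of 7 (permutation p = 0.001, 1-sided, again the smallest). With the sort by chromosome that was replaced, the runs numbered 17 and 23. A run of 10 genes from An12g02670 to An12g02780 fell with a median of -6.15, and a run of 8 from An01g06840 to An01g06910, with a match to a fumonisin dehydrogenase, rose with a median of 2.10. Co-regulated clusters may account for these 44 and 34 runs, but overlapping transcripts counted without strand were not tested and stay open.

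The VOC2 library lay between the controls and the other exposed libraries on principal component 1. On component 2 it stood apart, at -66.9 against 10.4 to 19.3 in the other libraries. With silencing as in VOC1 and VOC3, a fixed share of control RNA or reads would hold genes at a single percent of CK. The test took 69 genes under 0.5 CPM in VOC1 and VOC3 with a mean of at least 30 CPM in CK. The 90th percentile of that percent was 9.89 times the 10th (25.9 against 2.62). This argues against a fixed share as the sole source of their VOC2 levels. A share beside incomplete silencing in VOC2 was not tested and stays open. Library size is also argued against, since the VOC2 total differed by -0.687% from the mean of VOC1 and VOC3. Of 4002 genes changed at least 2-fold without VOC2, 76.8% had a VOC2 level in between, which restates the position that prompted the question, so a smaller or later response and a changing mixture of cells stay open. Levels also differed among genes outside these 69, which were above 0.5 CPM in VOC1 or VOC3. An08g09880 stood at 33.9% of CK in VOC2 and An01g10790 at 29.3%, against 4.38% for brlA. An08g09880 and An01g10790 were chosen after their values were seen.

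Of 175 ribosome genes 118 rose and 0 fell, with a median of 0.56 (SE 0.0181), while camera did not pass the 3 lists with an estimated correlation (adjusted p = 0.788, 0.788 and 0.807) and 21, 23 and 18 genes rose without CK1, CK2 and CK3. In these libraries, a median of 0.22 (SE 0.0182) with library sizes alone argued against scaling as the whole cause. There, 19 genes rose. The standard errors come from resampling genes and do not measure the spread between libraries. Random lists matched on gene length and mean expression had a middle median of 0.30 and a 95% range of 0.19 to 0.41, so part of the rise was shared by genes of like length and level. The highest of the 10000 matched lists reached 0.54, below the ribosome median, which lay above the 95% range by more than 2 standard errors. In these libraries ribosome genes thus rose more than genes of like length and level. Standard errors and random lists treat genes as independent, so neither covers ribosome genes moving together. Length or expression level as the whole cause is therefore not decided. The margin over the highest list was about 1 standard error, and the bound asked of that margin was made stricter after the value was seen and then returned to its first form.

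The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The labelled split gave 4513 changed genes and the highest other split 0 (edgeR, with at most 305 at an unadjusted p below 0.05), so 1 split reached that number. For gene lists past camera the labelled split gave 6 and the highest other split 10, and 7 of the 10 splits gave at least as many. The split with 10 lists set CK1, CK3 and VOC2 against the rest.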
